A study of Mus musculus with 18 samples.

How the data were processed

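Total RNA of immortalised mouse embryonic fibroblasts was measured on 18 single-colour Illumina bead arrays. The cells were wildtype or lacked the kinases JNK1 and JNK2 (called KO here). Per the labels, they grew on culture inserts in the same medium before (day 0) or during co-culture with differentiating human epidermal keratinocytes, and the inserts were changed every second day, which gave the samples of days 2, 4 and 6. Each array held RNA of 1, 2 or 3 pooled inserts. The 8 groups are the combinations of 2 genotypes and 4 days, with 1 array per genotype at day 0, 2 at day 2, 2 at day 4 and 4 at day 6. All inserts of a genotype came from 1 cell line, so the p-values measure the spread between arrays of single or pooled culture inserts and not between embryos or lines.

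The deposited table of non-normalized values held, per the file headers, a mean bead intensity for each of 45121 probes and 18 arrays, with a linear scale and no sign of a subtracted background in the values. Beside each intensity stood a deposited detection p-value. The authors also deposited a matrix of log2 values. By comparison with the intensity table, each of these values lay within 0.00500 of the log2 of the quantile-normalized intensities, with no background subtraction. How the arrays were scanned and how the detection p-value was computed is not stated in the labels.

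The detection p-values were of 2 kinds. On 12 arrays the dimmest probes had p near 1, as in a 1-sided test. On the other 6 arrays (day 6 replicates 2, 3 and 4 of both genotypes) the dimmest probes had p near 0, as in a 2-sided test, and these were converted to 1-sided values. The same 6 arrays had higher mean intensities, from 581 to 653 against 392 to 482, and more probes with a detection p-value under 0.01, from 44.9% to 45.8% against 37.3% to 40.8%. They are called the second processing set below, and the other 12 the first. The first holds day 6 replicate 1 of both genotypes, so that set and day can be separated only through those 2 arrays. Results are given beside the values with the set as a block and within each set.

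Intensities were background-corrected and quantile-normalized with neqc (normexp on the detection p-values, offset 16) of limma 3.58.1 in R 4.3.3. Probes with a detection p-value under 0.01 on at least 2 arrays were kept (26407). A single gene symbol was known for 34763 of the probes, 18 had several and 10340 had none. For a gene with several probes past the filter (5338 genes) the one with the highest mean signal stood for it. This left 13106 genes and 5022 probes without a single symbol, together 18128 features. Where no array of a group had a gene detected, also where that group is 1 of several averaged, the fold is given as a lower bound, with the values of that group raised to the lowest signal counted as detected on each of its arrays. Interactions, responses of single genotypes, differences of these responses and values under the alternatives are given as log2 values without such a bound. Arrays have no counting depth, so only their number and the signal over background limit the precision.

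A linear model with 1 mean per group was fitted to all 18 arrays with limma (lmFit, eBayes with an intensity trend). The day 6 groups hold arrays of both processing sets, so the spread, shared by all comparisons, also includes the difference between the sets. Log2 differences are given with their standard error, and adjusted p-values are Benjamini-Hochberg values over all features within a comparison, 2-sided, with a threshold of 0.05. KO was compared with wildtype at days 2, 4 and 6 and over the mean of these 3 days. Day 2 was compared with day 0 in the mean of both genotypes, and day 6 with day 2 in the mean and in each genotype. The interaction asked whether the genotype difference changed between days 2 and 6. Day 0 has 1 array per genotype, so its genotype difference is given as values, and in the comparison of day 2 with day 0 the lone arrays were assumed to vary like the other groups.

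The shift of 33 gene lists, written before the data were examined, was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within each comparison. The lists were JNK kinases and upstream kinases, AP-1 and immediate early genes, growth factors acting on keratinocytes, chemokines and inflammatory cytokines, NF-kB feedback genes, fibrillar collagens and matrix, basement membrane, matrix proteases and inhibitors, TGF-beta response genes, contractile and myofibroblast genes, Wnt and BMP pathway, cell cycle, p53 targets and cell cycle inhibitors, interferon-stimulated genes, MHC class I and antigen presentation, NRF2 and glutathione, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid stress, heat shock, glucocorticoid response genes, insulin-like growth factor binding, Hox and positional identity, X and Y linked sex genes, and markers of keratinocytes, simple epithelia, fibroblasts, endothelium, macrophages and leukocytes, skeletal muscle, cartilage and bone, adipocytes, and neural and neural crest cells. Camera with a correlation estimated from the residuals and fry, which asks only whether the members of a list move, were run beside it. Day 0 lists were placed among 10000 random lists matched on mean level in 20 bins.

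Genes were named by a rule also fixed before the data were examined. Mapk8 and Mapk9 were named with all probes. For KO against wildtype at day 6, the 10 largest differences in each direction were named among genes past the threshold whose groups of arrays did not overlap, and for other comparisons the 5 largest in each direction. Of each list with an adjusted p under 0.05, or with at least 1 in 4 measured members past the threshold, up to 4 members could be named, those past the threshold with the largest differences, or the 2 largest as values where none passed, and the text gives the first of these. Marker lists of other cell types were each described once, and for day 0 the 5 largest differences in each direction were named.

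The tests, lists, named-gene rule and the alternatives on background correction, scaling, source of values, filters, probes, samples in the fit, replicate blocks, weights, trend, thresholds and left-out arrays were chosen before the data were examined. The alternatives on the processing set, the conversion of detection p-values, the day 6 KO replicates 2 and 4 and the crossed replicate numbers at day 4 were chosen after seeing the data, as were the test of the difference between the genotypes' responses and those that tested the lists under median scaling, the sets and the replicate block, and the interferon list without wildtype replicate 2 of day 6. The replicate numbers were checked as a pairing of the genotypes. Deviations from the group mean correlated across features at 0.567, 0.110, 0.249 and 0.157 for the day 6 arrays of equal number, and at -0.368 to 0.243 for those of different number, so the number was used as a block only among the alternatives. Arrays of 1 group correlated at 0.971 to 0.992 across features, which are not independent replicates, and no pair of arrays shared more than 0.0155% of its intensities.

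The tests were checked on simulated data with the spread and background of these arrays. At day 6, 53% of genes changed 2-fold and 82% of those changed 4-fold were recovered, 91.1% and 100% in the brighter part of the genes, and 2 of 137 calls were false. At day 2, 33% and 76% were recovered, and 8 of 117 calls (6.84%) were false. False calls were 7 of 125 (5.6%) at day 4, 11 of 172 (6.4%) over the mean of days, 2 of 127 for day 2 against day 0 and 12 of 173 (6.94%) for day 6 against day 2, in 1 simulation each. A raised list of 25 genes was called and 0 of 32 others. The simulated genes varied independently of each other, and none was shifted between the processing sets. The simulation therefore does not show how often lists of correlated genes, or genes that differ between the sets, are called falsely. Figures were drawn with matplotlib 3.10.9. No sample was left out.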

Results

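The arrays measured the transcripts of mouse embryonic fibroblasts that fed differentiating human keratinocytes from a culture insert, with and without the stress kinases JNK1 and JNK2. These kinases phosphorylate Jun and other members of the AP-1 family of transcription factors. The 18 arrays hold 9 wildtype and 9 double-knockout (KO) samples, with 1 array per genotype before co-culture (day 0), 2 at day 2, 2 at day 4 and 4 at day 6. Per the labels the inserts were changed every second day, so the day is that of the keratinocyte culture, and the fibroblasts of each later day had shared only its last interval. Mean bead intensity per array ran from 392 to 653, and 37.3% to 45.8% of the probes were detected. The first principal component held 56.8% of the variance and set every KO array apart from every wildtype array. The second held 13.7% and parted the 6 arrays of the second processing set (34.90 to 43.79) from the other 12 (-39.22 to -13.08). Day 6 replicate 1 of both genotypes, outside that set, lay at -16.56 and -17.54, beside days 2 and 4.

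**Figure D1:**
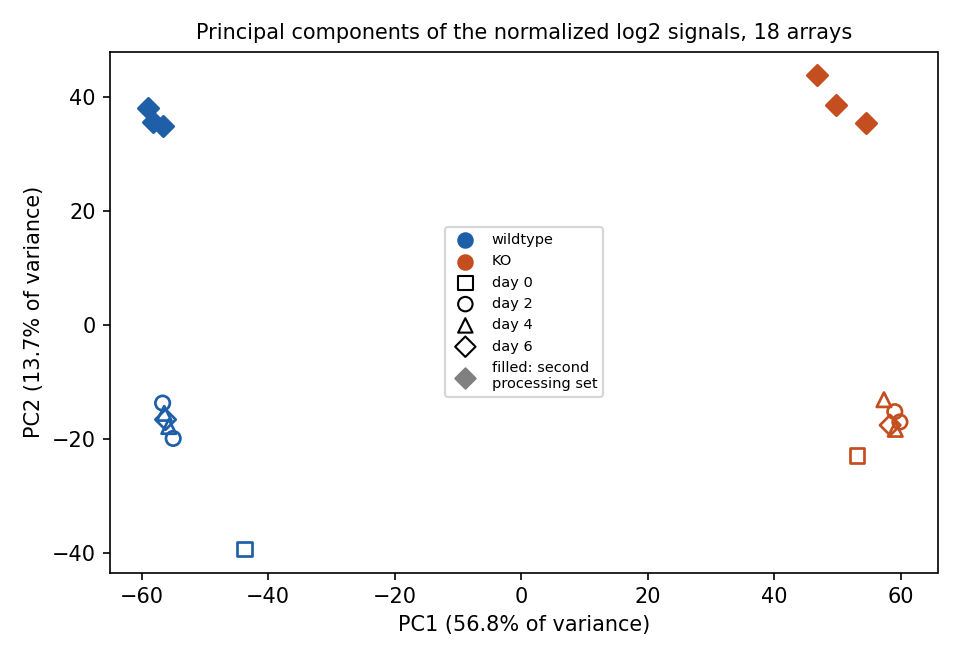
Scores of the 18 arrays on the first principal component (x axis, 56.8% of the variance) and the second (y axis, 13.7%), in units of log2 signal; each point is an array, blue for wildtype and orange for KO, with the marker giving the day (square 0, circle 2, triangle 4, diamond 6) and a filled marker the second processing set. The 9 KO and the 9 wildtype arrays lie on opposite sides along the x axis.

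The targeted genes were read in every sample first. Mapk9, which encodes JNK2, lay between 10.07 and 10.49 (normalized log2 signal) on the 9 wildtype arrays and between 4.51 and 5.60 on the 9 KO arrays. At day 6 it was lower in KO, at -5.41 ± 0.16 (log2 difference ± standard error, adjusted p = 9.02e-15). At days 4 and 2 it was at -4.99 ± 0.23 and -5.36 ± 0.23, and over the mean of days 2, 4 and 6 at -5.25 ± 0.12 (adjusted p = 5.34e-17). The Mapk9 probe read here was detected on 9 wildtype and 5 KO arrays, and a second Mapk9 probe on 9 wildtype and 0 KO arrays. The other Mapk9 probes were detected on 8 and 3 wildtype arrays and 0 KO arrays, too near the background in wildtype for the size of a loss to be read. Mapk8, which encodes JNK1, was dim in both genotypes. Its tested probe lay between 5.44 and 6.47 on the wildtype and 5.71 and 6.36 on the KO arrays and was detected on all of them, with a difference of -0.22 ± 0.21 at day 6 (adjusted p = 0.555). A Mapk8 probe detected on 7 wildtype and 9 KO arrays was at -0.50 ± 0.24 at day 6, not past the threshold, and the rest were detected on 4 and 5 arrays or on none. The labels do not say which part of either gene was deleted, so a probe outside that part shows nothing of the knockout.

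The main comparison asked how fibroblasts without JNK1 and JNK2 differed from wildtype at day 6 of the time course, with 4 arrays per genotype. The chemokine Cxcl15 was at least 280-fold higher in KO, the morphogen Bmp4 at least 172-fold, the matrix proteoglycan Prelp at least 156-fold, the LIM-domain protein Crip2 at least 92.9-fold and the adhesion molecule Cadm1 at least 52.8-fold, each against wildtype arrays without detection. The secreted ligand Wnt6 was higher by 6.15 ± 0.27, the fatty acid elongation enzyme Hsd17b12 by 6.23 ± 0.26, the microtubule protein Map2 by 5.51 ± 0.13 and the homeobox gene En2 by 5.46 ± 0.24. Epb41l4a was at least 32.5-fold higher. In the other direction Dlk1, an inhibitor of adipocyte differentiation, was lower, at -8.87 ± 0.73, the peptide hormone Cck at -7.81 ± 0.28, the basement membrane linker Nid1 at -7.30 ± 0.30 and the receptor Gpr149 at -7.20 ± 0.31. KO replicate 2 stood apart from the other KO arrays for Dlk1 (9.39 against at most 4.42) and Cck (5.50 against at most 4.34). The homeobox genes Hoxc6 and Hoxb7 were at -7.15 ± 0.25 and -7.00 ± 0.23. Prostacyclin synthase (Ptgis) and thrombomodulin (Thbd) were at least 73.6-fold and 63.3-fold lower, Plp2 was at -6.22 ± 0.20 and Snhg18 at -6.00 ± 0.23. All 20 were named as the 10 largest differences in each direction. By the naming rule, the 4 KO arrays of each had to lie entirely above or below the 4 wildtype arrays. Across all features 4617 (25.5%) separated in this way, against 2.86% by chance. Dlk1, Cck, Gpr149, Hoxb7 and Plp2, and below Hoxb5 and Ctsk, were detected on no KO array of the first set. Their differences rest partly on KO values at the background, so the sizes are less certain than the standard errors show.

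By limma, 5152 features passed the threshold at day 6, 2677 of them higher and 2475 lower in KO. They held 4286 named genes, 2226 higher and 2060 lower, and 1996 features differed at least 2-fold. The count was 6061 with the processing set as a block, 3608 within the first set (1 array per genotype at day 6, with the spread taken from days 2 and 4) and 4458 within the second (3 per genotype). Scaling each array to the same median gave 3615, with 42.8% of them higher in place of 52.0%.

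**Figure D2:**
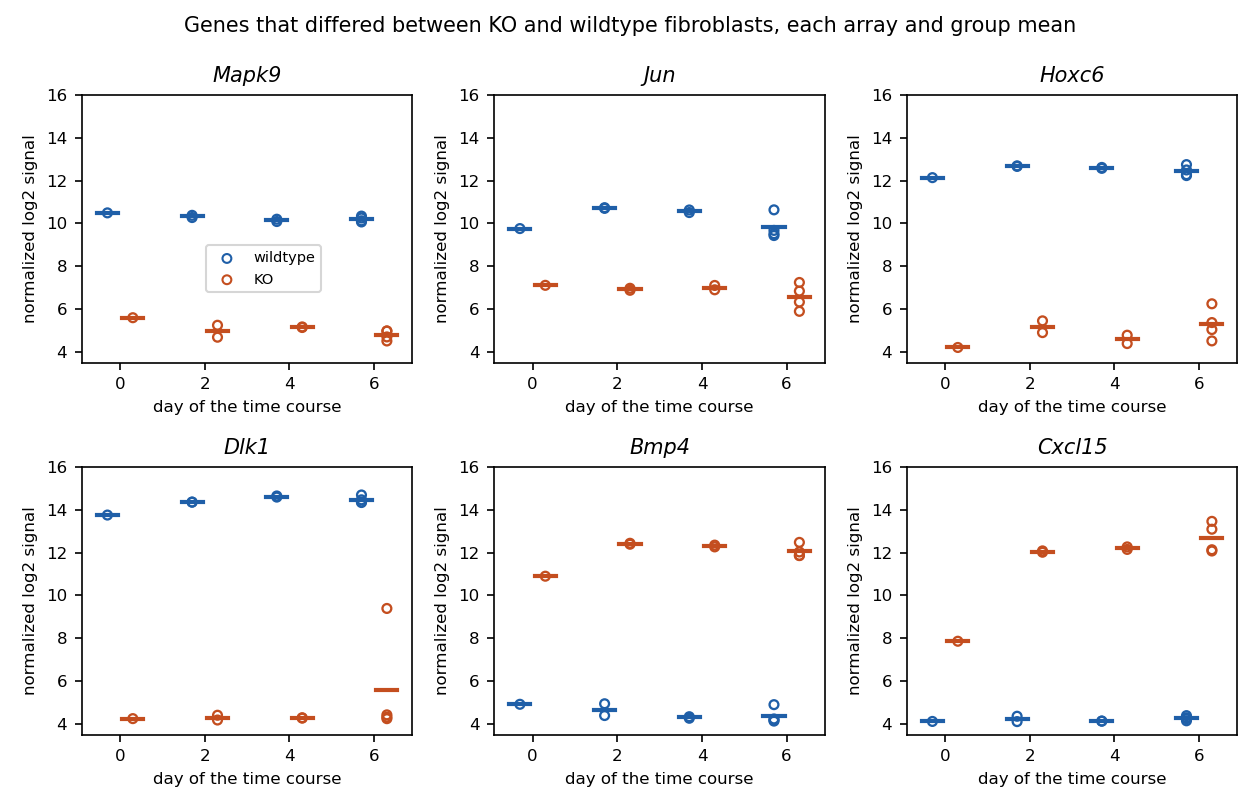
Normalized log2 signal (y axis) of Mapk9, Jun, Hoxc6, Dlk1, Bmp4 and Cxcl15 against day of the time course (x axis), 1 panel per gene; circles are single arrays, blue for wildtype and orange for KO, and horizontal bars are group means. Mapk9 lies between 10.07 and 10.49 on wildtype and between 4.51 and 5.60 on KO arrays, and Dlk1 is at 9.39 on 1 KO array of day 6 and at 4.42 or below on the other 8.

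Of the 33 gene lists, 13 shifted at day 6 by camera, and 1 of them, the Hox genes, also with a correlation estimated from the data. Hox and positional identity genes mark where along the body a cell arose. Of 24 measured, 12 were lower in KO and 0 higher, the same counts as adjusted over the list alone (adjusted p = 2.61e-09, and 0.0122 with an estimated correlation). Of these members Meis1 (-1.79) and Meis2 (-0.89), both lower, and Tbx15, not past the threshold, are not Hox genes. The list is called Hox genes for short. Beside Hoxc6 and Hoxb7, Hoxb5 was lower, at -5.68 ± 0.23, and Hoxb2 was at least 32.7-fold lower. Of 9 adipocyte markers 6 were lower (7 adjusted over the list alone) and 0 higher, among them the adipogenic regulator Pparg (-4.45 ± 0.30) and lipoprotein lipase, Lpl (-3.73 ± 0.29). The member with the largest fall was Dlk1, given above as an inhibitor of adipocyte differentiation, so its fall does not mark a loss of adipocyte character. This list had an adjusted p of 0.000131, and 0.232 with an estimated correlation. Of 10 insulin-like growth factor binding genes 8 were lower and 2 higher, also adjusted over the list alone (adjusted p = 0.000937, and 0.261 with an estimated correlation). Igfbp5 (-4.63 ± 0.43) and Igfbp6 (-3.86 ± 0.22) were lower, and Igfbp2 (3.44 ± 0.35) was higher. Of 13 fibroblast markers 6 were lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0136, and 0.485 with an estimated correlation). Dpt was at -3.38 ± 0.33 and Cd34 at -2.78 ± 0.18.

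AP-1 and immediate early genes include the direct targets of JNK. Of 22, 9 were lower and 2 higher, also adjusted over the list alone (adjusted p = 0.0221, and 0.538 with an estimated correlation). Jun itself was lower, at -3.24 ± 0.26, as was the phosphatase Dusp1, which switches off stress kinases, at -1.39 ± 0.13. Egr2 was higher by 2.31 ± 0.49. Egr3 was at -1.59 ± 0.47 and another of its probes at 0.29 (adjusted p = 0.644). The call of Egr3 ended without wildtype replicate 1 (adjusted p = 0.0537), KO replicate 2 (0.0553) or KO replicate 3 (0.0546). The shift of the list was lost without KO replicates 2 and 4 (adjusted p = 0.0743, in a range of 0.00647 to 0.0743 over the alternatives). Of 25 cell cycle genes 11 were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.000929, and 0.624 with an estimated correlation). The mitotic kinases Plk1 and Aurka were higher by 1.75 ± 0.17 and 1.51 ± 0.15. Of 17 hypoxia and glycolysis genes 9 were lower and 0 higher, also adjusted over the list alone (adjusted p = 0.00167, and 0.232 with an estimated correlation). Among them were the oxygen sensor Egln3 (-2.09 ± 0.21), the glucose transporter Slc2a1 (-0.99 ± 0.12) and Vegfa (-0.87 ± 0.17).

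Genes of the matrix and its turnover moved both ways. Of 26 fibrillar collagens and matrix genes 11 were lower and 6 higher, also adjusted over the list alone (adjusted p = 0.0306, and 0.624 with an estimated correlation). Fbln2 was lower, at -5.32 ± 0.27, and Col1a2 at least 17-fold lower, while the proteoglycan Ogn was higher by 4.70 ± 0.23. Of 21 matrix proteases and inhibitors 12 were lower and 6 higher (12 and 7 adjusted over the list alone). Gelatinase A (Mmp2, -5.80 ± 0.23) and cathepsin K (Ctsk, -5.74 ± 0.23) were lower and stromelysin-1 (Mmp3, 4.72 ± 0.52) was higher. The protease list had an adjusted p of 0.0176, and 0.538 with an estimated correlation. Both lists lost their call within the second set. The matrix list then had an adjusted p of 0.0504 (range 0.0101 to 0.0504) and the protease list 0.0847 (range 0.000887 to 0.0847).

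Of 16 contractile and myofibroblast genes 9 were higher and 2 lower (9 and 3 adjusted over the list alone). Smooth muscle actin (Acta2, 3.67 ± 0.21), Ankrd1 (2.87 ± 0.41) and Ccn1 (2.07 ± 0.30) were higher. Of 14 Wnt and BMP pathway genes 7 were higher and 2 lower (8 and 2 adjusted over the list alone). Beside Bmp4, Ccn5 was higher by 3.86 ± 0.21, and the Wnt inhibitor family member Dkk3 was lower, at -4.33 ± 0.36. Each of these lists had an adjusted p of 0.0147, and 0.261 with an estimated correlation.

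Interferon-stimulated genes are those that cells switch on in response to viruses and interferon. Of 23, 14 were lower and 4 higher (14 and 5 adjusted over the list alone). Usp18 was lower, at -5.35 ± 0.57, and Isg15 at -3.36 ± 0.51, and Rsad2 was at least 9.66-fold lower. The adjusted p of the list was 0.0112, and 0.707 with an estimated correlation. Its shift was lost within the second set (adjusted p = 0.0504, range 1.64e-06 to 0.0504). There wildtype replicate 2 stood apart, with a list mean of 6.81 among KO arrays at 6.77 to 7.52, while the other wildtype arrays of day 6 were at 8.17 to 9.03. Without it the list mean difference went from -1.09 to -1.53 (adjusted p = 1.64e-06, and 0.434 with an estimated correlation). Of 11 MHC class I and antigen presentation genes 6 were higher and 0 lower, also adjusted over the list alone. The peptide transporter Tap2 was higher by 1.80 ± 0.21 and Cd74 at least 6.75-fold. The adjusted p of this list was 0.0404, and 0.624 with an estimated correlation. The call held in 1 of 8 alternatives (adjusted p from 0.0212 to 0.398, and 0.0727 with the set as a block). Of the 13 calls, 12 held with the set as a block, 12 within the first set (1 array per genotype, as above), 9 within the second, 12 with a replicate block and 11 without KO replicates 2 and 4.

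**Figure D3:**
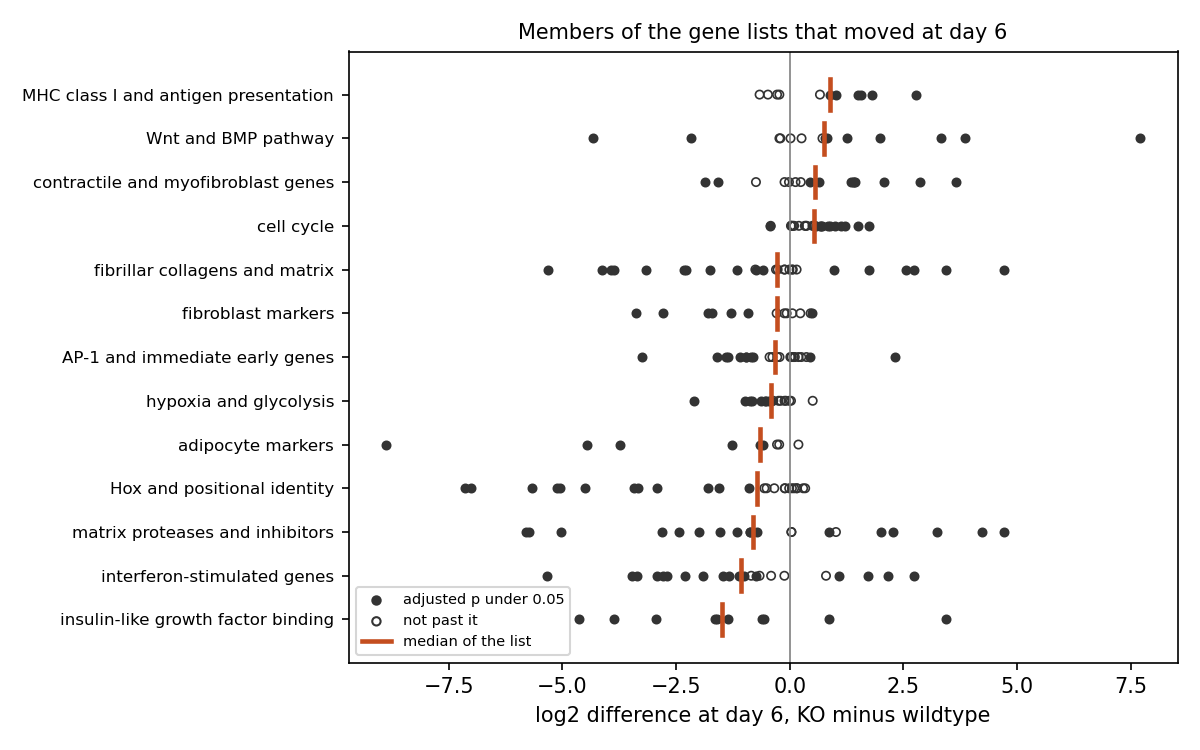
Log2 difference between KO and wildtype at day 6 (x axis) for the measured members of the 13 shifted gene lists (y axis, 1 row per list); each point is a gene, filled where it passed the threshold, and the orange bar is the median of the list. Of 24 Hox and positional identity genes 12 are lower and 0 higher, and of 25 cell cycle genes 11 are higher and 1 is lower.

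The other 20 lists did not pass the test at day 6. Chemokines and inflammatory cytokines split, with 6 of 24 higher and 9 lower (7 and 9 adjusted over the list alone, adjusted p = 0.393). Prostaglandin E synthase (Ptges, -5.54 ± 0.35) and Ccl5 (-5.39 ± 0.23) were lower, and Il33 (3.38 ± 0.30) was higher. Growth factors acting on keratinocytes were higher in 9 and lower in 9 of 26, also adjusted over the list alone (adjusted p = 0.849), with Ptn at -3.83 ± 0.39, Igf2 at 3.52 ± 0.44 and Fgf10 at -2.91 ± 0.17. NF-kB feedback genes were higher in 3 and lower in 4 of 12 (adjusted p = 0.393; Tnfaip2 at -5.13 ± 0.21). Basement membrane genes were higher in 3 and lower in 7 of 15 (adjusted p = 0.192), with Lama5 at 3.20 ± 0.27 and Nid2 at -2.73 ± 0.25 beside Nid1. TGF-beta response genes were higher in 5 and lower in 3 of 13 (5 and 4 adjusted over the list alone, adjusted p = 0.7; Tgfbi at -3.03 ± 0.34). p53 targets and cell cycle inhibitors were higher in 3 and lower in 4 of 16 (4 and 4 adjusted over the list alone, adjusted p = 0.764), with the inhibitors Cdkn2b and Cdkn1a at -3.82 ± 0.24 and -2.84 ± 0.24. NRF2 and glutathione genes were higher in 8 and lower in 6 of 19 (8 and 7 adjusted over the list alone, adjusted p = 0.764), with Aldh3a1 at 4.59 ± 0.28, the metallothionein Mt2 at -4.31 ± 0.17 and Nqo1 at -4.29 ± 0.15.

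Of 14 cholesterol synthesis genes 4 were higher and 0 lower (adjusted p = 0.208; Mvk at 1.89 ± 0.18). Of 18 unfolded protein and amino acid stress genes 4 were higher and 2 lower (4 and 4 adjusted over the list alone, adjusted p = 0.849). Of 12 heat shock genes 4 were higher and 2 lower (adjusted p = 0.685; Hspb1 at 2.88 ± 0.19). Of 14 glucocorticoid response genes 4 were higher and 5 lower (5 and 5 adjusted over the list alone, adjusted p = 0.212; Angptl4 at -3.73 ± 0.22). Of 9 JNK and upstream kinases 3 were higher and 1 lower (adjusted p = 0.7; Map3k1 at 1.60 ± 0.13). Of 8 X and Y linked sex genes 3 were higher and 0 lower (adjusted p = 0.258; Xist at 1.46 ± 0.26). Where a list of day 6 has 1 pair of counts here, the counts adjusted over the list alone were the same.

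The remaining marker lists of other cell types did not pass the test. Of 15 keratinocyte markers 2 were higher and 1 lower (adjusted p = 0.794; involucrin, Ivl, at least 6.38-fold lower). Of 6 simple epithelial markers 1 was higher and 2 lower (adjusted p = 0.406; Krt19 at least 15.6-fold lower). Of 6 endothelial markers 1 was higher and 0 lower (adjusted p = 0.767; Flt1 at 3.24 ± 0.25). None of 4 macrophage markers passed the threshold (adjusted p = 0.991), with Lyz1 at -0.47 ± 0.25 and Adgre1 at 0.23 ± 0.22. None of 6 skeletal muscle markers did (adjusted p = 0.797), with Des at -0.74 ± 0.32 and Mylpf at 0.50 ± 0.26. Of 9 cartilage and bone markers 1 was higher and 2 lower (adjusted p = 0.767; Msx1 at 4.15 ± 0.24). Of 9 neural and neural crest markers 4 were higher and 1 lower (adjusted p = 0.0856; Map2 above). Mean and median had opposite signs in 7 of the 20 lists, those of JNK kinases, growth factors, NF-kB, p53, glucocorticoid response, endothelium and macrophages. The tested direction of the cartilage list was opposite to both.

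The genotype difference was read again at days 4 and 2, with 2 arrays per genotype each. Nearly the same genes led at both days. Dlk1 was at least 965-fold lower in KO at day 4 and at least 852-fold lower at day 2, and Gpr149 at least 186-fold and 241-fold, Nid1 at least 224-fold and 312-fold, and Cck at least 141-fold and 156-fold. Hoxc6 was at least 229-fold lower at day 4 and at -7.50 ± 0.36 at day 2. Cxcl15 was at least 183-fold and 164-fold higher, Bmp4 at least 196-fold on both days and Prelp at least 209-fold and 204-fold. Crip2 was higher by 6.61 ± 0.24 at day 4 and at least 120-fold at day 2, Hsd17b12 at least 63.4-fold at day 4 and Wnt6 at least 75.2-fold at day 2. Jun was lower, at -3.57 ± 0.36 and -3.80 ± 0.36, and Usp18 at -5.95 ± 0.81 and -6.56 ± 0.81.

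At day 4, 3458 features passed the threshold (1775 higher, 1683 lower; named genes 1459 and 1401), of which 2119 differed at least 2-fold, and at day 2 there were 3619 (1807 higher, 1812 lower; named genes 1469 and 1534), of which 2216 did. The counts were 4453 and 4685 with the set as a block and 4989 and 5176 within the first set, which holds all arrays of these days. Without wildtype replicate 2 of day 4 the first count was 2219. Without wildtype replicate 1 or 2 or KO replicate 2 of day 2 the second was 2331, 2408 or 2332, and median scaling gave 1900 and 2227, with 39.6% and 28.1% of them higher in place of 51.3% and 49.9%. The genotype differences of days 2, 4 and 6, which share no arrays, correlated across features at 0.893 to 0.915, which are not independent replicates. Of features called at days 2 and 6, 1570 were higher and 1594 lower on both, against 266.8 and 247.4 by chance, and 1 was opposite. The chance counts assume independent calls. The days compare the same 2 cell lines with 1 shared estimate of the spread, so the overlap shows only that these lines differ on each day. All 2639 features called at the 3 days had the same direction, 1304 higher and 1335 lower.

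At day 4, 12 lists shifted and at day 2, 9 lists, and at each day the Hox genes were the 1 list that also shifted with an estimated correlation. Of 24 Hox and positional identity genes 13 were lower at day 4 (15 adjusted over the list alone) and 14 at day 2 (14 adjusted over the list alone), and none was higher. Their adjusted p was 2.22e-12 at day 4 and 1.45e-11 at day 2, and 0.00403 and 0.00529 with an estimated correlation. Of 23 interferon-stimulated genes 13 were lower and 3 higher at both days, and adjusted over the list alone 15 were lower at day 2. Their adjusted p was 0.00275 and 0.00024, and 0.56 and 0.563 with an estimated correlation. AP-1 genes were lower in 5 and higher in 1 of 22 at day 4, and lower in 8 (9 adjusted over the list alone) and higher in 1 at day 2. Their adjusted p was 0.044 and 0.00202, and 0.473 and 0.477 with an estimated correlation. Matrix proteases were lower in 10 (11 adjusted over the list alone) and higher in 5 of 21 at day 4, and lower in 11 and higher in 5 at day 2. Their adjusted p was 0.00737 and 0.00149, and 0.382 and 0.477 with an estimated correlation. Cell cycle genes were higher in 6 of 25 at day 4 and in 10 at day 2 (7 and 13 adjusted over the list alone, with 1 lower at day 2). Their adjusted p was 0.0106 and 0.00531, and 0.56 and 0.604 with an estimated correlation.

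Insulin-like growth factor binding genes were lower in 6 (7 adjusted over the list alone) and higher in 1 of 10 at day 4, and lower in 7 and higher in 1 at day 2. Their adjusted p was 0.000943 and 0.00272, and 0.35 and 0.477 with an estimated correlation. Fibroblast markers were lower in 5 and 6 of 13, also adjusted over the list alone (adjusted p = 0.0148 and 0.0158, and 0.382 and 0.48 with an estimated correlation). Adipocyte markers were lower in 4 and 5 of 9 (6 and 5 adjusted over the list alone, with 1 higher at day 2; adjusted p = 0.000235 and 0.00202, and 0.274 and 0.418 with an estimated correlation).

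Some shifts were called at 1 of these days. At day 4, 5 of 17 hypoxia and glycolysis genes were lower, also adjusted over the list alone, and 7 of 16 contractile genes were higher, with 2 lower (8 and 2 adjusted over the list alone). Of 14 Wnt and BMP pathway genes 6 were higher and 3 lower (7 and 3 adjusted over the list alone), and of 12 NF-kB feedback genes 4 were lower and 2 higher (5 and 2 adjusted over the list alone). The adjusted p of these 4 lists was 0.0279, 0.0291, 0.0246 and 0.0424, and 0.35 for each with an estimated correlation. The Wnt shift was lost with a replicate block (adjusted p = 0.0504, range 0.0117 to 0.0504). The NF-kB shift was lost with a replicate block (0.0517) or within the first set (0.0558, range 0.0136 to 0.0558). At day 2, 5 of 14 cholesterol synthesis genes were higher, also adjusted over the list alone, with mevalonate kinase (Mvk) at 2.22 ± 0.25. The adjusted p of this list was 0.0326, and 0.48 with an estimated correlation, and the call was lost with median scaling (0.0891, range 0.0125 to 0.0891). Whether these lists differ between days was tested only between days 2 and 6, by the interaction given last.

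Over the mean of days 2, 4 and 6, each day with equal weight, the same 5 genes led in both directions as at day 2. Cxcl15 was at least 203-fold, Bmp4 at least 187.5-fold and Prelp at least 188-fold higher, Crip2 at least 103-fold and Wnt6 at least 69.3-fold. Dlk1 was at least 728-fold lower, Nid1 at least 222.5-fold, Gpr149 at least 187-fold, Cck at least 170-fold and Hoxc6 at least 181-fold. Of the AP-1 genes, 10 were lower and 2 higher, also adjusted over the list alone (adjusted p = 0.0102, and 0.461 with an estimated correlation). Jun was at -3.53 ± 0.19, Dusp1 at -1.82 ± 0.10 and Dusp6 at -1.75 ± 0.12. Of 24 Hox and positional identity genes 16 were lower (adjusted p = 1.11e-09, and 0.0105 with an estimated correlation). Of 23 interferon-stimulated genes 17 were lower and 4 higher (adjusted p = 0.00114, and 0.562 with an estimated correlation). Of 25 cell cycle genes 14 were higher and 1 lower (adjusted p = 0.00227, and 0.562 with an estimated correlation). The counts of these 3 lists were the same adjusted over the list alone. Matrix proteases were lower in 12 and higher in 5 (12 and 6 adjusted over the list alone; adjusted p = 0.00974, and 0.461 with an estimated correlation). Insulin-like growth factor binding genes were lower in 8 and higher in 1 (8 and 2 adjusted over the list alone; 0.00135, and 0.41). Hypoxia and glycolysis genes were lower in 7 (0.00974, and 0.41), adipocyte markers in 7 (0.000601, and 0.348) and fibroblast markers in 7, with 2 higher (0.0141, and 0.461), also adjusted over the list alone. In total 6877 features passed the threshold, 3622 higher and 3255 lower (named genes 2914 and 2713), and 2040 of them differed at least 2-fold. The count was 7731 with the set as a block, 7079 within the first set and 5141 with median scaling, with 37.8% of these higher in place of 52.7%.

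Before co-culture there was 1 array per genotype, so day 0 gives values without a test. The genotypes already differed widely in the same medium. Dlk1 was at least 548-fold lower in KO, Gpr149 at least 195-fold, Hoxc6 at least 179-fold, Hoxb7 at least 147-fold and the lectin Clec4d at -7.50 (log2). Hsd17b12 was at least 60.3-fold higher, Slc24a3 at least 50.7-fold, Epb41l4a at least 50.4-fold, Crip2 by 6.11 and the protease inhibitor Slpi by 6.00. In all, 2854 features differed at least 2-fold, 1323 higher and 1531 lower. Of the features called at day 6, 4644 (90.1%) had the same sign at day 0, against 67.8% of all features. The differences of day 0 correlated with those of the later days at 0.723 to 0.748 across features.

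The next comparison asked how fibroblasts differed between the first co-culture interval (day 2) and day 0, in the mean of both genotypes. The serum amyloid Saa3 rose by 7.05 ± 0.27 (log2), haptoglobin (Hp) at least 85.95-fold and the siderophore-binding lipocalin Lcn2 by 6.41 ± 0.25 (log2), and matrix Gla protein (Mgp) rose by 3.96 ± 0.26. Ifi27l2a, an interferon-stimulated gene, rose at least 13-fold. The glutathione transferases Gsta1 (-3.62 ± 0.45) and Gsta2 (-3.31 ± 0.34) fell, as did the cytokine Il11 (-3.06 ± 0.35) and Ramp3 (-3.04 ± 0.32), and Dppa5a fell at least 8.95-fold. In all, 1731 features passed the threshold, 1011 up and 720 down (named genes 881 and 565), and 708 changed at least 2-fold. The count was 2862 with the set as a block, 3695 within the first set and 453 with median scaling, with 65.8% of them up in place of 58.4%. It was 528 without the KO day 0 array, 820 without the wildtype one and 1011 to 1147 without any 1 of the 4 day 2 arrays.

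**Figure D4:**
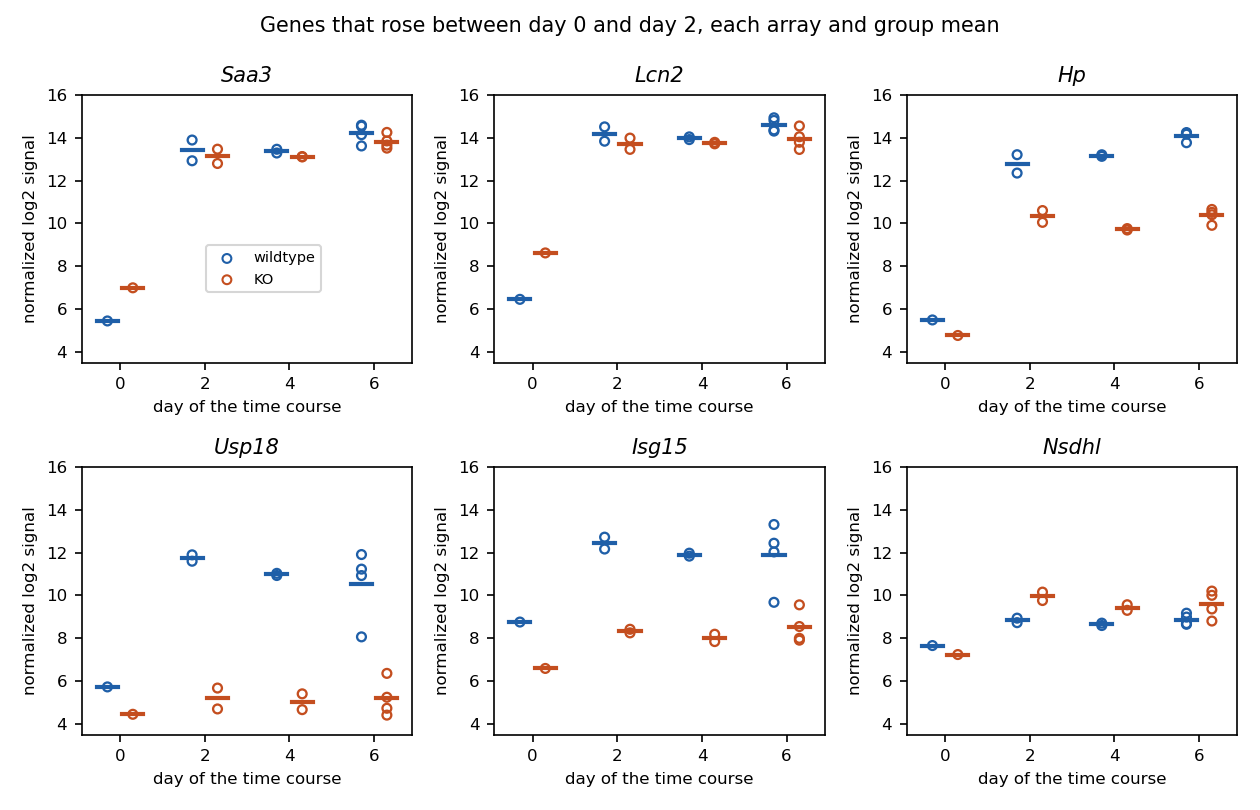
Normalized log2 signal (y axis) of Saa3, Lcn2, Hp, Usp18, Isg15 and Nsdhl against day of the time course (x axis), 1 panel per gene; circles are single arrays, blue for wildtype and orange for KO, and horizontal bars are group means. From day 0 to day 2, Saa3 goes from 5.44 to 13.41 in wildtype and from 6.99 to 13.13 in KO, and Usp18 from 5.73 to 11.75 in wildtype and from 4.45 to 5.19 in KO.

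Between day 0 and day 2, 13 lists moved at the preset correlation. Day 0 had 1 array per genotype, so a shift through co-culture is not separated from variation between single cultures. The cholesterol synthesis, NF-kB feedback, NRF2 and glutathione, and glucocorticoid response lists, 4 in all, also moved with an estimated correlation, each with an adjusted p of 0.00616. Of 14 cholesterol synthesis genes 12 rose (14 adjusted over the list alone) and 0 fell (adjusted p = 3.3e-16). Nsdhl rose by 1.95 ± 0.28, Mvd by 1.69 ± 0.23 and Sc5d at least 3.085-fold. The call of Sc5d ended with median scaling (adjusted p = 0.0666). Of 12 NF-kB feedback genes 7 rose and 0 fell (8 and 1 adjusted over the list alone; adjusted p = 1.78e-06), led by Nfkbiz at 2.45 ± 0.20. Of 19 NRF2 and glutathione genes 10 fell and 3 rose (11 and 3 adjusted over the list alone; adjusted p = 1.61e-06). Gsta4 was at -1.95 ± 0.17 and the cystine transporter Slc7a11 at -2.10 ± 0.37, where another probe gave 0.42 (adjusted p = 0.545). Of 14 glucocorticoid response genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 1.94e-05). Lcn2 led them, with Dusp1 at 1.64 ± 0.16. The medium held hydrocortisone at day 0 as well.

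Of 23 interferon-stimulated genes 17 rose (21 adjusted over the list alone) and none fell (adjusted p = 1.01e-14, and 0.205 with an estimated correlation). Usp18 rose at least 9.67-fold, Oasl2 by 3.10 ± 0.64, Ifit3 by 2.84 ± 0.63 and Isg15 by 2.72 ± 0.62. Of 11 MHC class I and antigen presentation genes 5 rose (9 adjusted over the list alone; adjusted p = 2.44e-06, and 0.205 with an estimated correlation), with Tap2 at 2.09 ± 0.26. Of 24 chemokines and inflammatory cytokines 10 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 1.72e-09, and 0.122 with an estimated correlation). Saa3 and Lcn2, given above, led the rises, and Il11 was the 1 that fell. The interleukin-1 receptor antagonist Il1rn rose by 2.64 ± 0.38. Of 26 fibrillar collagens and matrix genes 13 rose (16 adjusted over the list alone; adjusted p = 2.33e-10, and 0.121 with an estimated correlation). Ogn rose by 2.44 ± 0.29, the cross-linking enzyme Loxl1 by 1.85 ± 0.25 and Col6a2 by 1.84 ± 0.27. Of 25 cell cycle genes 6 fell (12 adjusted over the list alone; adjusted p = 6.84e-08, and 0.248 with an estimated correlation), with the replication helicase subunit Mcm3 at -1.35 ± 0.27.

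Of 13 fibroblast markers 4 rose (6 adjusted over the list alone; adjusted p = 0.000514, and 0.208 with an estimated correlation), with Snai2 at 1.73 ± 0.21 and Pdgfra at 1.73 ± 0.29. Of 10 insulin-like growth factor binding genes 3 rose, also adjusted over the list alone (adjusted p = 0.00459, and 0.225 with an estimated correlation; Igfbp7 at 1.36 ± 0.16). Of 14 Wnt and BMP pathway genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.00965, and 0.205 with an estimated correlation; Ccn5 at 2.17 ± 0.26). Of 9 adipocyte markers 2 rose (4 adjusted over the list alone; adjusted p = 0.0261, and 0.248 with an estimated correlation; Scd1 at 1.15 ± 0.18).

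Several of these gene calls rested on 1 day 0 array, without which the comparison held only the other genotype. Without the wildtype day 0 array the log2 change was 0.74 for Usp18 (adjusted p = 0.78, from no detection at KO day 0), 1.67 for Oasl2 (0.326), 2.45 for Ifit3 (0.123), 1.75 for Isg15 (0.285), 2.03 for Ifi27l2a (0.334), -1.67 for Gsta1 (0.146), -1.70 for Gsta2 (0.0494) and -0.92 for Gsta4 (0.037). Without the KO day 0 array it was 6.02 for Usp18 (0.00146), 3.22 for Ifit3 (0.0576), -5.56 for Gsta1 (3.67e-05), -2.97 for Gsta4 (5.92e-07), -1.86 for Il11 (0.0489), 1.17 for Nsdhl (0.138), 0.85 for Mvd (0.211), -0.88 for Mcm3 (0.284) and 0.84 for Scd1 (0.0869).

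The difference between the inserts of day 6 and those of day 2 was asked for next, again in the mean of both genotypes. Fos fell most, at -2.57 ± 0.49, followed by the STAT5 feedback inhibitor Cish at -1.89 ± 0.24, the mRNA decay factor Zfp36 at -1.76 ± 0.29, Klf10 at -1.62 ± 0.35 and Egr1 at -1.52 ± 0.41. The acetyltransferase Crebbp rose at least 3.97-fold, Smoc1 at least 2.82-fold, stem cell factor (Kitl) at least 3.05-fold, Zmiz1 by 1.52 ± 0.30 and Arrdc2 at least 2.36-fold. Another probe of Crebbp, Zmiz1 and Arrdc2 gave -0.12, -0.01 and -0.13, none past the threshold. In all, 600 features passed the threshold, 319 up and 281 down (named genes 198 and 238), and 91 changed at least 2-fold. With the processing set as a block, which parts most day 6 arrays from all day 2 arrays, 2 features passed, within the first set 3 did, Egr1 turned to 0.17 in both, and median scaling, which put the median of all features at 0.27, gave 1888, 89.7% of them up in place of 53.2%. Without any 1 of the 4 day 2 arrays the count was 3 to 14, and without the other day 6 arrays in turn 4 to 82, but 3473 without wildtype replicate 1 of day 6 and 3926 without KO replicate 1. Without any 1 day 2 array the calls of all 10 genes named here except Cish ended (adjusted p from 0.0547 to 0.172), and each of these 9 also ended without 1 or more of the day 6 arrays of replicates 2 to 4 (0.0516 to 0.0937).

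Of 26 fibrillar collagens and matrix genes 4 rose from day 2 to day 6 (13 adjusted over the list alone; adjusted p = 0.000179), with Col1a1 at 1.16 ± 0.25 and Dcn at 1.00 ± 0.19. Of 17 hypoxia and glycolysis genes 5 rose (7 adjusted over the list alone; adjusted p = 0.00198; Pdk1 at 0.72 ± 0.15). Of 15 basement membrane genes 2 rose (4 adjusted over the list alone; adjusted p = 0.0166; Col4a1 at 0.84 ± 0.18). Each of these 3 lists had an adjusted p of 0.499 with an estimated correlation. Their shifts held with the set as a block (adjusted p = 0.037, 0.000552 and 0.037) and kept their direction within the first set. In the mean of both genotypes these 2 alternatives estimate the same change, from 1 day 6 array per genotype, so they are not separate checks. Across features the changes of wildtype and KO within the first set correlated at 0.0362. The calls of Col1a1, Dcn, Pdk1 and Col4a1 ended without any 1 day 2 array (0.0576 to 0.146). Of 22 AP-1 genes 5 fell (7 falling and 1 rising adjusted over the list alone; adjusted p = 0.00469, and 0.499 with an estimated correlation). Of 13 fibroblast markers 3 rose (4 rising and 1 falling adjusted over the list alone; adjusted p = 0.0494, and 0.607 with an estimated correlation). The AP-1 and fibroblast shifts turned direction with the set as a block (adjusted p = 0.949 and 0.805) and within the first set (0.493 and 0.627), and the fibroblast shift held in 0 of 6 alternatives (range 0.059 to 0.805).

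Within wildtype, 7 features passed the threshold between days 2 and 6 (2720 at an unadjusted p under 0.05), all named genes. Hp rose by 1.32 ± 0.22 and Bcl6 by 1.14 ± 0.14. Cish (-2.58 ± 0.34), Dpysl3 (-1.57 ± 0.25), Esr1 (-1.50 ± 0.24) and Dusp1 (-1.21 ± 0.16) fell, and Foxq1 fell at least 2.05-fold. The call of each ended without wildtype replicate 2 of day 2 (adjusted p from 0.205 to 0.676; Hp then at 0.89). That of Cish, Dpysl3, Esr1 and Foxq1 also ended without replicate 1 (0.117 to 0.276). That of Hp, Dpysl3, Esr1 and Foxq1 ended without replicate 3 or 4 of day 6 (0.079 to 0.123), and that of Foxq1 without its replicate 2 (0.0792). The count was 0 without replicate 2 of day 2, 4 without its replicate 1 and 2 with the set as a block. It was 3 without replicate 3 or 4 of day 6 and 1061 without replicate 1 of day 6.

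In wildtype the AP-1 list shifted down (1 falling, 7 adjusted over the list alone; adjusted p = 9.43e-05, and 0.463 with an estimated correlation). So did interferon-stimulated genes, without a called member (0.0132, and 0.92), but this rested on replicate 2 of day 6. Without it the change in their list mean went from -0.50 to -0.06 and the call ended (0.831, range 9.15e-09 to 0.831). Hypoxia and glycolysis genes shifted up, with 0 members past the threshold and 6 adjusted over the list alone (9.43e-05, and 0.228). Matrix genes did too, with 0 members and 9 adjusted over the list alone (0.000415, and 0.627). The AP-1 shift was lost with the set as a block (0.154, range 9.38e-07 to 0.365) and the matrix shift too (0.0785, range 0.000136 to 0.0785).

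In KO, 0 features passed by limma between days 2 and 6 (3087 at an unadjusted p under 0.05). There were 1967 without KO replicate 1 of day 6 and 1 without KO replicate 2 of day 2. The list of matrix genes shifted up (adjusted p = 0.00202, and 0.68 with an estimated correlation), as did chemokines (0.0162, and 0.717) and NF-kB feedback genes (0.0162, and 0.311). Basement membrane genes (0.0162, and 0.68) and matrix proteases (0.0179, and 0.686) also shifted up. Adjusted over the list alone, 1 matrix, 2 basement membrane and 1 protease gene passed the threshold. The matrix shift was lost with the set as a block (0.283, range 0.000354 to 0.283) and the NF-kB shift within the first set (0.0863, range 0.00139 to 0.0863). The chemokine shift was lost in 3 of 6 alternatives (range 0.00025 to 0.108).

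Whether the genotype difference itself changed between days 2 and 6 was tested by the interaction. By limma 0 features passed (711 at an unadjusted p under 0.05), also with the set as a block and within the first set. For 5 lists the difference shifted up, that is toward KO at day 6, with 0 members past the threshold, also adjusted over the list alone. They were interferon-stimulated genes (adjusted p = 0.000511, and 0.823 with an estimated correlation), matrix proteases (0.0104, and 0.564), AP-1 (0.0145, and 0.564), NF-kB feedback (0.0175, and 0.405) and contractile genes (0.0249, and 0.564). Among the members, Ifit2 was at 1.33 ± 0.44, Mmp13 at 1.71 ± 0.83, Fosb at 1.25 ± 0.48 (not detected in KO at day 2), Nfkbiz at 0.74 ± 0.28 and the smooth muscle actin Actg2 at 1.52 ± 0.61, each with an adjusted p of 1. The interferon shift rested on wildtype replicate 2 of day 6. Without it the interaction in the list mean went from 0.63 to 0.19 and the call ended (0.175, range 0.000101 to 0.175). The NF-kB and contractile shifts were lost within the first set (0.783 and 0.109) and without KO replicates 2 and 4 of day 6 (0.144 for both). Their ranges were 0.00299 to 0.783 and 0.00609 to 0.144. The protease shift turned direction within the first set (0.998, range 0.00281 to 0.998).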

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

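The 6 tests that weigh explanations below, on the processing sets, on KO replicate 2 and on KO replicate 4 of day 6, were chosen only after the results they bear on were seen. Those on the sets and on KO replicate 2 were also revised after a first run. The distance of a single array from its group and the interaction were fixed before.

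In each group of 4 arrays at day 6, the gap of the farthest array to its neighbour was divided by the range of the group, for the mean signal, the share of probes detected and the 84 genes named at that day. Of 172 such groups 14 passed the 95% limit of Dixon's ratio, against 8.6 expected by chance. Replicate 1, the array of the first processing set, stood apart in wildtype for the mean signal (392, ratio 0.903), the share of probes detected (39.95%, ratio 0.958), Bmp4 (ratio 0.871), Wnt6 (0.9), Egr2 (0.859), Igf2 (0.886) and Des (0.931). It stood apart in KO for the mean signal (441, ratio 0.876), the share detected (40.8%, ratio 0.943) and Des (0.833). KO replicate 2 stood apart for Dlk1 (9.39, ratio 0.965) and Cck (5.50, ratio 0.956), wildtype replicate 4 for Krt19 (7.64, ratio 0.837) and wildtype replicate 2 for Adgre1 (4.80, ratio 0.877).

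The genotype difference changed between day 2 and day 6 by the interaction for 5 gene lists, with adjusted p-values of 0.000511 for interferon-stimulated genes, 0.0104 for matrix proteases, 0.0145 for AP-1, 0.0175 for NF-kB feedback and 0.0249 for contractile genes. No feature passed the same test, and no list passed it with an estimated correlation. The interferon call ended without wildtype replicate 2 of day 6 (adjusted p = 0.175). The contractile call ended without KO replicates 2 and 4 of day 6 (adjusted p = 0.144), as did the NF-kB call. The protease shift turned direction within the first set. The AP-1 call held in 7 of 7 alternatives at the preset correlation.

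The change between days 2 and 6 runs along the processing sets. At day 6 itself 3765 of all features (20.8%) differed between the sets with genotype in the fit, so the sets may account for part or all of the 600 calls. Within the first set 3 features passed between days 2 and 6. The stage of the keratinocyte culture and the processing set cannot be told apart here, because the first set holds 1 day 6 array per genotype.

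In KO replicate 2 of day 6, several transcripts of wildtype cells were higher than in other KO arrays. Of 19 features detected on every wildtype array and on no KO array of the first set, 16 (84.2%, 33.3% by chance) were higher there than in KO replicates 3 and 4 of its set. A first selection of 10 features, undetected on all other KO arrays, gave 80% and was replaced because it forced low values in replicates 3 and 4. Among 18274 probes undetected on every array of the first set, 32.7% were higher in replicate 2. The share of the wildtype level above that of replicates 3 and 4 was uneven, at 3.03% for Dlk1, 1.34% for Gpr149 and 0.60% for Cck (quartiles over the features 0.17% and 1.17%). Whether wildtype RNA entered this sample cannot be told, because 1 admixture would give even shares while most of these features lie near the background. Their median level was 1.14% of wildtype, against 0.455% and 0.421% in replicates 3 and 4, a ratio of 0.383, which argues against the background of the second set as the whole source. A contribution of that set stays open, since 7 and 5 of the 19 were detected in replicates 3 and 4, against 13 in replicate 2 and, by the selection, 0 on the first-set KO arrays. No biological explanation was tested, and without this array and replicate 4 the day 6 count was 4585 against 5152.

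KO replicate 4 of day 6 lay toward the KO sample of day 0. Its distance from KO replicates 2 and 3 followed the difference between day 0 and co-culture with a slope of 0.34. The same slope was -0.25 for replicate 2 and -0.09 for replicate 3, and the 3 sum to 0 by construction, so part of it reflects replicate 2 lying the other way. Against replicate 3 alone, replicate 4 had a slope of 0.29 and replicate 2 of -0.11. Of 127 features at least 4-fold higher in co-culture than at day 0, 58 (45.7%) lay over 1 (log2) below the other KO arrays (46 below replicate 3 alone). A mixture gives such a fall only where most of the RNA is of day 0, and Saa3 would then fall as well. Saa3 was at 13.85 in replicate 4, against 14.25 and 13.52 in replicates 2 and 3 and 6.99 at day 0. This argues against day 0 RNA as the source of these falls. Wildtype replicate 4 shares the second set and the pooling of 3 inserts, and had a slope of -0.12 (-0.09 against wildtype replicate 3 alone). So the 2 did not give this shift in wildtype, but 1 array of the other genotype cannot settle it for KO. Some genes stood at the day 0 level and others did not (Hopx 5.99 against 8.80 and 8.77, and Lcn2 13.46), and a difference in the state of these cultures stays open and untested.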

How the results depend on the processing

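The alternatives on the processing set, detection p, day 6 KO replicates 2 and 4, the crossed day 4 numbers, the lists under median scaling, the sets and the replicate block, and the interferon list without wildtype replicate 2 of day 6 were chosen after seeing the data. Where no reason is given, the cause was not tested. A threshold of 0.01 or of 2-fold lowers a count by construction.

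The difference between the genotypes, each from 1 cell line, was the firmest result. The day 6 count (5152) and the count over the mean of the 3 days (6877) stayed within 1.5 times under every alternative except the 2-fold minimum, which left 1996 and 2040, and leaving out single arrays gave 4557 to 5179 and 6181 to 7138. The deposited detection p gave 5159 at day 6, and the crossed day 4 numbers 4445 at day 4. At day 4 (3458) and day 2 (3619) median scaling gave 1900 and 2227, the 2-fold minimum 2119 and 2216, an adjusted p under 0.01 gave 2218 and 2394, and leaving out single arrays 2219 to 2563 and 2331 to 2493. All 41 differences named at day 4, day 2 and the mean of days kept direction and call in every alternative, in 286, 294 and 504 comparisons. Of the 84 named at day 6, 79 did, and 2333 of 2351 comparisons kept both. Adgre1, not past the threshold, turned to -0.10 with array weights and -0.00972 within the second set.

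Day 2 against day 0 (1731) gave 453 with median scaling, 3965 with only the compared groups in the fit, 1103 with a random replicate block, 3606 with array weights, 708 at 2-fold, 704 at an adjusted p under 0.01, 2862 with the set as a block, 3695 within the first set and 528 to 1147 without single arrays. Of 32 named genes 21 kept their call throughout.

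Median scaling moved the median of all features at day 2 from 0.03 to -0.08, and put it at 0.27, 0.20 and 0.33 for day 6 against day 2 in the mean, wildtype and KO and at 0.12 for the interaction, so its counts there are not relative to the other genes.

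Day 6 against day 2 depended on most choices. The mean of both genotypes (600) gave 1888 with median scaling, 171 without a detection filter, 1168 over every probe, 39 with only the compared groups, 2 and 20 with a fixed and a random replicate block, 7012 with array weights, 53 with weights by inserts, 201 without an intensity trend, 91 at 2-fold and 4 at an adjusted p under 0.01. It gave 2 with the set as a block, 3 within the first set, 7 without KO replicates 2 and 4, 1 with both changes, and 3 to 3926 without single arrays. Egr1 turned to 0.17 with the set as a block, within the first set, and with the block and without both KO arrays. Wildtype (7) gave 25 with quantile normalization alone, 24 with the deposited matrix, 1 with median scaling, 23 without a filter, 0 with only the compared groups, 3255 with array weights, 3 at an adjusted p under 0.01, 2 with the set as a block and 0 to 1061 without single arrays. KO (0) gave 41 without a filter, 4250 with array weights, 6 without a trend, 1 within the first set, 1 with the block and without both arrays, and 0 to 1967 without single arrays. The interaction (0) gave 27 with array weights, 1 with the block and without both arrays, and 0 without any single array. The highest counts without a single array, in wildtype, KO and their mean, were those without replicate 1 of day 6.

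Lists past the threshold by camera, with an estimated correlation and by fry were 13, 1 and 25 at day 6, 12, 1 and 22 at day 4, 9, 1 and 22 at day 2, and 9, 1 and 28 over the mean of days. They were 13, 4 and 17 for day 2 against day 0, 5, 0 and 1 for day 6 against day 2, 4, 0 and 2 in wildtype, 5, 0 and 1 in KO, and 5, 0 and 0 for the interaction. With the set as a block day 6 against day 2 had 10 lists, and within the first set 13, with 8 in wildtype and 3 for the interaction, which also had 3 without KO replicates 2 and 4. AP-1 genes and fibroblast markers turned direction between days 2 and 6 with the set as a block (adjusted p = 0.949 and 0.805) and within the first set (0.493 and 0.627), as did matrix proteases in the interaction within the first set (0.998). Without wildtype replicate 2 of day 6 the interferon list lost its call between days 2 and 6 in wildtype (0.831) and in the interaction (0.175), and kept it at day 6 (1.64e-06) and over the mean of days (4.81e-06) at the preset correlation, but not with an estimated one (0.434 and 0.429).

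Signal over background limits what small differences can be seen. In simulated data at day 6, 53% of genes changed 2-fold were recovered, and 91.1% in the brighter part. A block for the array chip was not run, since the labels name no chip. Within the first set the spread came from days 2 and 4, since day 6 had 1 array per genotype there. No array of the second set was of day 0, 2 or 4, so within that set only day 6 gave a value.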

Other observations

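The test of the difference between the genotypes' responses to co-culture was chosen only after the responses of single genes were seen, while the counts of other splits were fixed before.

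The responses of wildtype and KO to co-culture were read side by side. Given as values (mean of 2 day 2 arrays minus 1 day 0 array, log2), Saa3 changed by 7.97 in wildtype and 6.14 in KO, Hp by 7.29 and 5.56 (from no detection at KO day 0), Lcn2 by 7.72 and 5.10 and Mgp by 2.77 and 5.14. Il11 changed by -1.86 in wildtype and -4.26 in KO. Interferon-stimulated genes had a median change of 2.32 in wildtype and 0.80 in KO (0.61 with undetected values set to the detection level), chemokines 1.64 and 0.41 (1.56 and 0.35), and NRF2 and glutathione genes -1.47 and -0.68. Cholesterol synthesis genes had 0.73 and 1.47. Across features the responses of the genotypes correlated at 0.383, which are not independent replicates, and 61.7% had the same sign.

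Before co-culture, several lists already stood apart between the genotypes, as values from 1 array each, beside 10000 random lists of the same level. The median difference of Hox genes was -1.45 (percentile 0), of insulin-like growth factor binding genes -1.22 (percentile 0), of NRF2 and glutathione genes -0.80 (percentile 0), of adipocyte markers -0.85 (percentile 0.1; -0.77 with undetected values at the detection level) and of AP-1 genes -0.56 (percentile 0.05). MHC class I genes were at 1.17 and cell cycle genes at 0.68 (both percentile 100), and chemokines at 0.54 (percentile 99.95; 0.52 with the detection level). Interferon-stimulated genes were at 0.14 (percentile 76.8; 0.01 with the detection level). Over the mean of days 2, 4 and 6, 17 of these 23 were lower in KO and 4 higher (adjusted p = 0.00114, and 0.562 with an estimated correlation). The day 0 median of this list hides members that already differed. At day 0 Ifit3 was at 8.89 in wildtype and 5.42 in KO, and Isg15 at 8.76 and 6.59. Usp18 was at 5.73 and 4.45 (not detected in KO), while Oasl2 was at 5.27 and 5.59.

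A hypothesis is that KO fibroblasts answer co-culture with a weaker interferon response. Each genotype has 1 day 0 array, so every p-value of the difference between responses borrows its spread from other groups. In the difference of the responses (KO minus wildtype, day 2 minus day 0), this list had a median of -1.86 over 23 genes and an adjusted p of 1.19e-11 by camera, but 0.317 with an estimated correlation, and 0 of its members passed the threshold. Usp18, not detected in KO at day 0, was at -5.28 ± 1.40 (adjusted p = 0.147). A weaker response in KO and variation between single cultures cannot be told apart for this list, because of the single day 0 arrays and because the members move together between arrays. By limma 43 features passed the threshold with that borrowed spread (1605 at an unadjusted p under 0.05; 168 with the set as a block and 674 within the first set), among them Lcn2 at -2.62 ± 0.49 (adjusted p = 0.0266), Vcam1 at -2.15 ± 0.40 (0.0254) and Gsta4 at 2.04 ± 0.34 (0.0133), which were picked after their values were seen. NRF2 and glutathione genes passed also with an estimated correlation (adjusted p = 5.76e-07, and 0.00489). This rests on the single day 0 arrays, with list means of 10.56 in wildtype and 9.47 in KO, against 8.98 to 9.16 on the 4 day 2 arrays, so a difference in response and variation between single cultures cannot be told apart there either. Cholesterol synthesis, chemokine, NF-kB, matrix protease and glucocorticoid response genes passed at the preset correlation alone (adjusted p from 5.48e-07 to 0.00559, and from 0.0569 to 0.317 with an estimated correlation), with the same limit.

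The genotype counts of day 6 and of the mean of the 3 days were higher than those of all other divisions tried. Every other division of day 6 mixes the 2 lines within each group, so its low count follows once the lines differ widely. The genotype counts of days 2 and 4 alone were not tested in this way. Each genotype came from 1 cell line, so the loss of JNK1 and JNK2 and other differences between the lines cannot be told apart. Of the 35 splits of the 8 day 6 arrays into 4 and 4, the real one included, 1 gave as many features as the real one (5152), and the highest other gave 5. Only 8 splits part the 4 pairs of equal replicate number, too few for a test of their own (highest other 0). Of 100 groupings within days, the real one included, 1 gave as many as the mean of the 3 days (6877), with 4313 the highest other. For day 6 against day 2, 4 of 100 groupings within genotypes, again with the real one included, gave at least the real count of 600, the highest 1273. Regroupings that exceed the real count point to a structure of the arrays other than day, and with the processing set as a block 2 features passed. Between days 4 and 2, within the first set, 2 features passed by limma (1520 at an unadjusted p under 0.05), Socs2 at -1.06 and Cygb at 0.98 (adjusted p = 0.0494 for both), named after their values were seen.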
